A study of Danio rerio with 40 samples.

How the data were processed

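The series holds 40 single-cell RNA sequencing libraries from zebrafish heart, each labelled as 1 cell. Per the labels' protocols, ventricles of adult fish of the EK strain, 6 months old, were dissociated with the enzyme mix Liberase DH at 37 °C, and cells were sorted that carried green fluorescence from a nuclear tcf21 reporter and excluded the dead-cell dye propidium iodide. The cells were then captured, and their RNA copied into libraries, on the Fluidigm C1, a microfluidic device that holds single cells in separate chambers. The labels name 1 group and no animal, batch or day for any cell.

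The deposited table gives expected counts per gene for every cell, that is, estimated numbers of reads that need not be whole. Per the submitters' processing notes the tools were Bowtie2 and RSEM 1.2.12 and the genome build was Zv9, and their roles and settings are not given in the sources used here. Reads of near-identical gene copies are divided by such an estimate, so values of close paralogs (the hsp70 copies, for example) are uncertain one by one. The protocol names no molecular identifiers, so reads are not independent molecules, and intervals and limits cover the counting of cells only.

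Levels were computed here from the deposited expected counts as counts scaled to a total of 1000000 over all genes of the cell (CPM). A gene was called detected in a cell at 5 or more expected reads, and a cell was kept if at least 2000 genes were detected. The filter kept 25 cells and left out 15, and no cell was removed or grouped by a marker gene. No doublet caller was run, since 40 libraries are too few for one. The choices of detection level, cell filter, gene lists, named genes and alternatives were made before the data were examined, except where a setting is said to have been added. The table has 33737 genes, of which 21939 (65.0%) have a symbol in the gene name table supplied with the data. Many of those symbols are in capitals and are printed as given. Symbols of the fixed lists were matched exactly, then ignoring case, then without the zebrafish copy letter, which found 495 of 614 symbols. A capital symbol can therefore stand for more than 1 copy, and the gene identifier is given where the symbol alone is ambiguous. cav1, the gene in the series title, had no symbol in that table, so the planned share of cells with cav1 and the planned ranking of genes by correlation with cav1 are not analysed here.

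Since no animal is named, the 40 cells count as 1 sample and there is no second group. No test was run, no p-value is given, and a standard deviation over cells describes the spread between cells of this sample. Shares of cells have a 95% Wilson interval, and a count of 0 cells is given with the upper limit that 3 cells of the total would allow. For the 27 fixed gene lists, co-variation was the mean pairwise Spearman correlation of the members detected in at least 10% of kept cells, for lists with at least 4 such members. It is given as a percentile among 10000 random lists of the same size matched on mean level in 20 bins. Variability was the median of log10 squared coefficient of variation minus a lowess fit on log10 mean (span 0.3), given as a percentile in the same way. A list was said to stand apart at or above the 97.5th percentile, or for variability also at or below 2.5. Genes are not independent replicates, so these percentiles describe the 25 libraries.

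Cells were clustered on the 500 genes of highest residual variability as log2(CPM + 1), z-scored and reduced to 10 principal components, with Ward linkage and the number of clusters from 2 to 6 of highest mean silhouette width. Stability was the adjusted Rand index over 100 draws of 50% of those genes, and the silhouette was set beside 100 tables with each gene shuffled over cells. Genes named in the text are members of the fixed lists, the 20 genes of highest mean among those detected in every kept cell (ribosomal and mitochondrial genes left out), and the 20 genes of highest residual variability detected in 20 to 80% of kept cells with a mean of at least 10 CPM. actn3b and mtus1a, named in the last paragraph, fall outside this rule and were looked up after the data were seen. Genes without a symbol were counted and, with 1 exception, not named. For other cell types, the number of cells with at least 50% of a marker list detected was counted, copies with the same symbol counting once.

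The steps were tested on simulated cells drawn from the means and totals of the kept cells, over 7349 genes. A list of 15 members with a shared factor stood apart in 20 of 20 simulations and one without it in 0 of 20, and 15 members with added spread were found in 20 of 20. The simulated cells took only means and totals from the data, and not the spread in genes detected at a given total. The 0 of 20 thus sets no limit on false calls among libraries that differ in genes detected, as the kept cells do. The 20 of 20 hold for the strengths of factor and spread simulated. With 200 genes changed between 2 simulated kinds of cell, the division into 2 clusters matched the truth with an adjusted Rand index of 1 at a 16-fold change and 0.559 at a 4-fold change. The number of clusters of highest silhouette was 6 at both folds where 2 had been simulated, and 2 with no change simulated, where the division into 2 did not match the 2 kinds (adjusted Rand index -0.00891), so the number of clusters is a weak measure here. On 2 principal components, an alternative added after the data were seen, it was 3 at 16-fold and 4 at 4-fold.

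Alternatives tried were other detection levels (any read, 20 reads, and the added level of 50 CPM), other cell filters (none, 1000 or 4000 genes), scaling by median-of-ratios size factors, other gene filters, other correlations, a correction for the number of genes detected, other clustering settings, and runs without single cells. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and statsmodels 0.14.6, and matplotlib 3.10.9 for the plots.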

Results

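To describe the epicardium at the level of single cells, transcripts were measured in 40 cells sorted from adult zebrafish ventricles for a nuclear tcf21 reporter. tcf21 encodes a transcription factor used as a marker of the epicardium, the cell layer that covers the heart. All cells belong to 1 group, and no animal was named, so the cells are described as 1 sample without tests. Total expected reads per cell ranged from 340293 to 5695770, with a median of 3008670. A median of 2153.5 genes per cell had at least 5 expected reads, from 161 in cell 1 to 10792 in cell 40, and the next highest cell, 15, had 4119. The 25 cells with at least 2000 genes were kept for the descriptions that follow. In these cells the 11 genes with a mitochondrial symbol made up a median of 1.57% of reads. In the 15 cells not kept they made up 4.35%, with up to 47.3% in cell 34. Genes without a symbol could not be counted as mitochondrial, so these shares are lower limits.

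**Figure D1:**
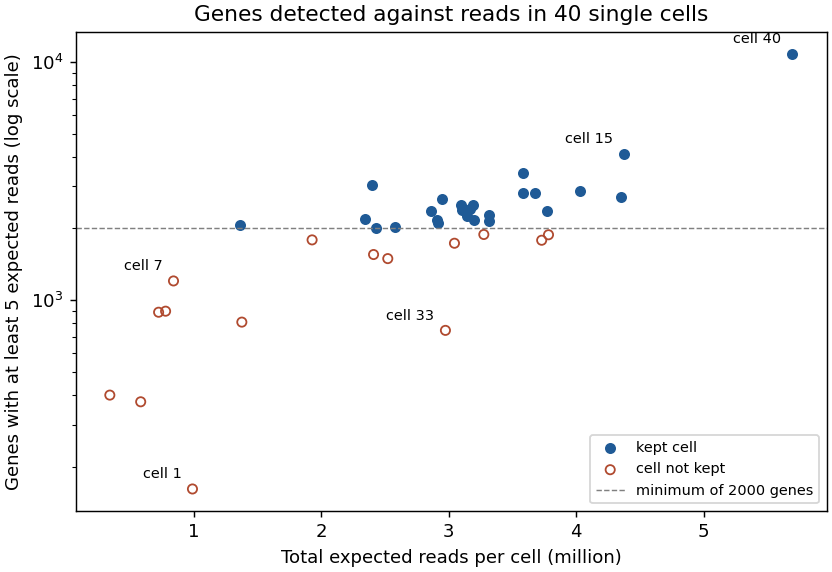
Genes with at least 5 expected reads (log axis) against total expected reads for each of the 40 cells, with kept cells as filled points, cells not kept as open points and the minimum of 2000 genes as a dashed line. Cell 40 lies above all others with 10792 genes, and cell 1 below all others with 161.

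TCF21 (ENSDARG00000036869), the gene behind the reporter, was detected in 24 of 25 kept cells (Wilson 95% interval 80.5 to 99.3%) and in 37 of all 40 (92.5%, 80.1 to 97.4). Its mean level in kept cells was 451.1 ± 434.7 CPM (SD over 25 cells). The 3 cells below the detection level were 7, 11 and 33, with 2, 2 and 3 reads. At 50 CPM or more, a level added after the data were seen, TCF21 was found in 22 of 25 kept cells. TBX18, another epicardial transcription factor gene, was detected in 19 of 25 (76.0%, 56.6 to 88.5) and the keratin gene krt8 in 24 of 25 at 3333 ± 3224 CPM. Of the 19 measured epicardial marker genes, 2 were detected in at least 90% of kept cells, 14 in 10 to 90%, 1 in fewer and 2 in none. At least 50% of the 16 epicardial marker symbols were detected in 6 of 25 kept cells, and reached 50 CPM in 3.

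The 9 other epicardial genes named in this paragraph were detected in 3 to 13 of the 25 kept cells each. ALDH1A2, which encodes an enzyme that makes retinoic acid, was detected in 6 of 25 kept cells (11.5 to 43.4%), and reached 50 CPM in 3. These were cell 15 with 3939.6 CPM, cell 25 with 2583 CPM and cell 40 with 433.3 CPM. podxl, which encodes a sialomucin of epithelial surfaces, was also detected in 6 and reached 50 CPM in the same 3 cells, at 235.6, 2465 and 767.6 CPM. jam2b, a junctional adhesion gene, was detected in 3 cells, which were again 15, 25 and 40. Cells 40 and 15 had the most genes detected of all cells, 10792 and 4119, so shared detection there may reflect their gene number. The Wilms tumor genes WT1 and wt1b were detected in 4 and 5 kept cells, BNC2 in 9, GATA5 in 8, HAND2 in 6 and tmem88b in 13. At any read above 0 in place of 5 reads, the shares of wt1b, podxl and BNC2 were 44.0%, 48.0% and 56.0%.

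**Figure D2:**
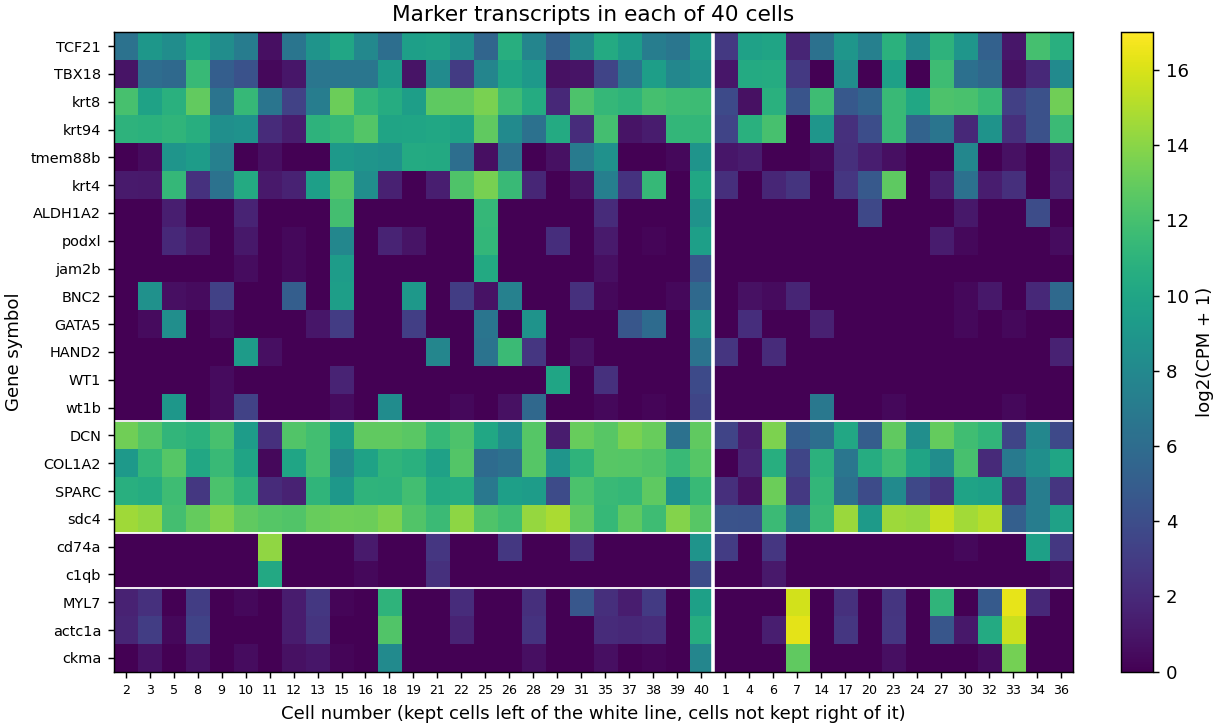
Levels as log2(CPM + 1) of marker genes (rows) in each of the 40 cells (columns), with kept cells left of the white line and cells not kept right of it. TCF21 is found in 37 cells, ALDH1A2 is high in cells 15 and 25, cd74a is highest in cell 11, and MYL7 and actc1a are highest in cells 7 and 33.

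Some genes of the extracellular matrix were detected in nearly every kept cell. Of 31 measured genes for collagens and fibrous matrix, 8 were detected in at least 90% of kept cells, 14 in 10 to 90%, 6 in fewer and 3 in none. The fibronectin gene FN1 (ENSDARG00000006526) was detected in 25 of 25 at 5121 ± 4434 CPM, and reached 50 CPM in 22. SPARC was detected in 25 at 1945 ± 1760 CPM, COL1A2 in 24 at 2595 ± 2230 CPM and the proteoglycan gene DCN in 24 at 4519.8 ± 3459 CPM. sdc4, which encodes a cell surface heparan sulfate proteoglycan, was detected in all 40 cells. At 10203 ± 7195 CPM it was among the 20 highest of the genes detected in every kept cell, ribosomal and mitochondrial genes left out. hapln1a, a hyaluronan link protein gene, was detected in 23 of 25 kept cells but reached 50 CPM in 11, and the hyaluronan synthase gene HAS2 was detected in 24 at 20.4 ± 15.2 CPM. The list of hyaluronan and proteoglycan genes had 3 of 20 members in at least 90% of kept cells. Members of the fibroblast marker list, which shares genes with the collagen list, held a median of 1.29% of reads in kept cells. At least 50% of the list was detected in 23 of 25, all but cells 11 and 29, and reached 50 CPM in 17. Cells 7 and 33, which were not kept, also had at least 50% of the list detected. The list held only 0.00881% and 0.0243% of their reads, so meeting this rule does not require a high share. PDGFRA was detected in 3 of 25, TNC (ENSDARG00000021948) in 1 and LUM in 3.

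Caveolae are flask-shaped pits of the cell membrane, and caveolin 1, one of their coat proteins, stands in the title of the series. cav1 itself is not analysed here. Of 11 other measured caveola genes, 0 were detected in at least 90% of kept cells, 6 in 10 to 90%, 2 in fewer and 3 in none. CAV2 was detected in 3 of 25 (4.17 to 29.96%), and its highest levels among kept cells were 223.5 CPM in cell 25 and 139.3 CPM in cell 40. CAV2 was not confined to kept cells: it was detected in 6 of all 40, and reached 50 CPM in 2 kept cells and in 5 of all 40. CAVIN1 (ENSDARG00000059362) was detected in 5 of 25 (8.86 to 39.1%), with 1429 CPM in cell 25 and 676.2 CPM in cell 15. CAVIN2 (ENSDARG00000071196) was detected in 13 at 406.5 ± 821.6 CPM and EHD2 (ENSDARG00000040362) in 13 at 281.2 ± 586.2 CPM. cavin4b was detected in 14 of 25 kept cells at 5 reads but reached 50 CPM in 1.

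Stress response transcripts were among the most abundant in these cells. In all, 218 genes were detected in every kept cell, of which 12 were ribosomal, 4 mitochondrial and 42 without a symbol. Of these, 28 belonged to a fixed list, 15 of them to the immediate early genes, which are switched on within minutes of a stimulus, and 6 to the heat shock genes. FOS had the highest mean of all genes with a symbol at 29278 ± 17461 CPM, followed by HSPA2 at 26587 ± 19026 CPM, hsp70.3 at 15885 ± 11588 CPM and hsp70.1 at 14024 ± 15271 CPM. A further ranking took the genes detected in every kept cell, with ribosomal and mitochondrial genes left out. Its 20 highest also held egr1, dnajb1b, JUNB, JUN, CSRNP1, BTG2, JDP2 (ENSDARG00000020133) and HSP90AA1. The cytoskeletal and translation genes actb2 and eef1a1l1 and the ubiquitin gene UBB were among the same 20. Immediate early genes held a median of 7.25% of reads in kept cells (1.80 to 20.2) and heat shock genes 5.05% (2.16 to 21.4). HSPA2 was not a member of the heat shock list, so this share and all other values of that list leave it out. Of 38 immediate early genes, 16 were detected in at least 90% of kept cells, and of 24 heat shock genes 9. The count of genes in every cell depended on the detection level and the cells included: it was 72 at 20 reads, 24 at 50 CPM and 41 over all 40 cells, and it was 218 without cell 40.

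**Figure D3:**
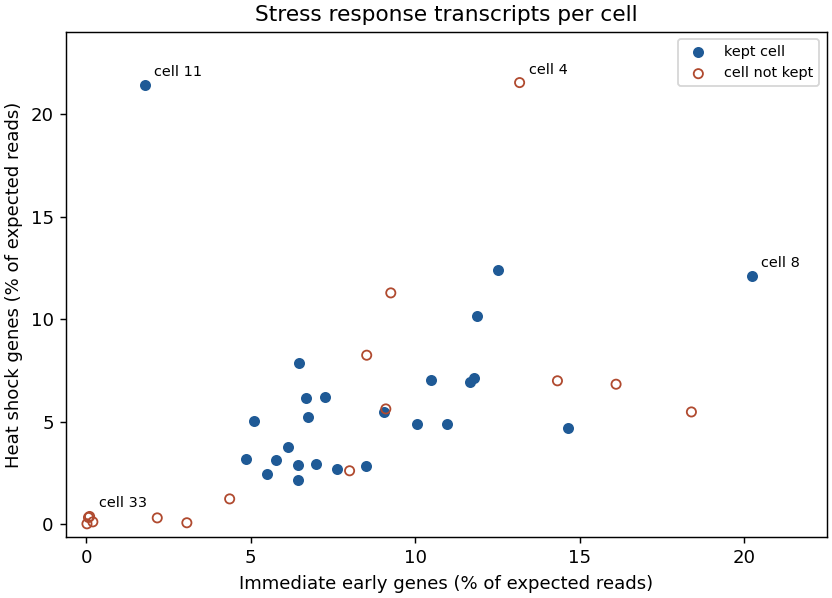
Heat shock genes against immediate early genes, both as percent of the expected reads of the cell, for each of the 40 cells, with kept cells as filled points and cells not kept as open points. Cell 11 has 21.4% heat shock and 1.80% immediate early reads, and cell 33 lies near 0 on both axes with 0.387% and 0.109%.

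The other fixed lists had few members in most cells. Of 33 measured cell cycle genes, 0 were in at least 90% of kept cells, 5 were in 10 to 90%, and 21 were in none. The 5 were hmgb2b in 11 of 25, HMGB2 (ENSDARG00000029722) in 10, PCNA and STMN1 (ENSDARG00000033655) in 4 and MCM5 in 3. Of 35 secreted ligand genes, 0 were in at least 90% and 13 in 10 to 90%, among them CXCL12 in 16, igf2b in 16 and the midkine gene MDK (ENSDARG00000036036) in 22. The retinoic acid list had 9 of 24 genes in 10 to 90%, with RDH10 (ENSDARG00000012369) in 13, and the list for Notch and Hedgehog signalling 8 of 18, with jag1b in 19. Among 21 genes of epithelial to mesenchymal transition, 1 was in at least 90% and 11 in 10 to 90%: MMP2 was detected in 23 of 25, VIM (ENSDARG00000010008) in 18 and twist1a in 12, and snai2 in 2. Of 28 genes of epithelial junctions and keratins, 3 were in at least 90% and 11 in 10 to 90%. Among them krt94 was detected in 23 of 25, krt15 in 20, krt4 in 18 and krt5 in 6, but krt5 reached 50 CPM in only 2. Of 30 oxidative phosphorylation genes, 26 were in 10 to 90% and 0 in at least 90%, and of 21 iron and oxidative stress genes 16 and 1, with fthl27 in 23 of 25.

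Transcripts of other cell types were searched for with 10 lists besides the epicardial and fibroblast ones. The cardiomyocyte list, with at least 50% of its 12 symbols detected, was found in kept cells 18 and 40 and in cells 7 and 33, which were not kept. Its genes held 1.13% of reads in cell 18 and 0.336% in cell 40, with MYL7, a cardiac myosin light chain gene, at 2107 and 826.7 CPM. In cell 18, 8 of the 12 cardiomyocyte symbols reached 50 CPM, while fibroblast markers held 1.42% of reads. Cell 18 stayed among the kept cells, and whether its library holds RNA of more than 1 cell was not tested. At least 50% of the macrophage list was found in cells 11 and 40. Cell 11 had 18914 CPM of cd74a and 7875 CPM of mhc2dab, both genes of antigen presentation to T cells, and 1245 CPM of the complement gene c1qb. TCF21 had 2 reads in this cell, COL1A2 had 1, and fibroblast markers held 0.00281% of its reads. Mural cell and neutrophil lists reached that share in cell 40 only, and the thrombocyte list, which includes FN1, in cells 2 and 40. The endothelial, erythrocyte, lymphocyte, neural or glial and pigment cell lists reached it in 0 of 25 kept cells and in 0 of 40. This allows a share of up to 12% and 7.5% for cells that meet the rule. It sets no limit on cells of those types, since the epicardial list itself met the rule in only 6 of 25 kept cells. In cell 26, endothelial markers held 0.162% of reads with 1 symbol detected. At 50 CPM in place of 5 reads, kept cells with at least 50% of a list were left for the cardiomyocyte list alone, apart from the epicardial and fibroblast lists. Counted together, 4 kept cells met the rule for any of the 10 lists, 3 without cell 40 and 15 with any read above 0.

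Some groups of genes varied together from cell to cell. Of the 20 lists with enough detected members, 9 stood in the top 2.5% of matched random lists. Some of these lists share genes, so the 9 are not separate groups. The fibroblast list shares members with the collagen list, and the epicardial list with the collagen and the epithelial junction lists. The strongest mean correlations were those of 6 cardiomyocyte genes (0.403, percentile 100), 9 fibroblast genes (0.341, 99.99), 6 caveola genes (0.310, 99.97), 4 macrophage genes (0.293, 97.66), 16 epicardial genes (0.216, 99.99), 22 collagen and matrix genes (0.215, 100) and 14 epithelial junction and keratin genes (0.208, 100). Immediate early genes (98.62) and oxidative phosphorylation genes (99.61) also passed that level. Heat shock genes did not (25.8), nor did genes of hyaluronan and proteoglycans (89.69), secreted ligands (74.59), retinoic acid (93.45), Notch and Hedgehog (71.66), epithelial to mesenchymal transition (96.49), complement (93.15), antigen presentation and interferon (76.92), the cell cycle (62.33), iron and oxidative stress (64.49) or mural cells (19.4). Without cells 5, 15, 25 and 40 the epithelial junction list stood at the percentile 78.04, and without cell 40 fewer than 4 cardiomyocyte and macrophage genes remained. Without cell 40 and with a correction for genes detected per cell, 4 lists stood in the top 2.5%, and the caveola (97.19), epithelial junction (93.26) and oxidative phosphorylation lists (94.92) did not. The immediate early list stood at 86.89 with median-of-ratios scaling, and the oxidative phosphorylation list to 86.95 after correction for genes detected per cell.

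**Figure D4:**
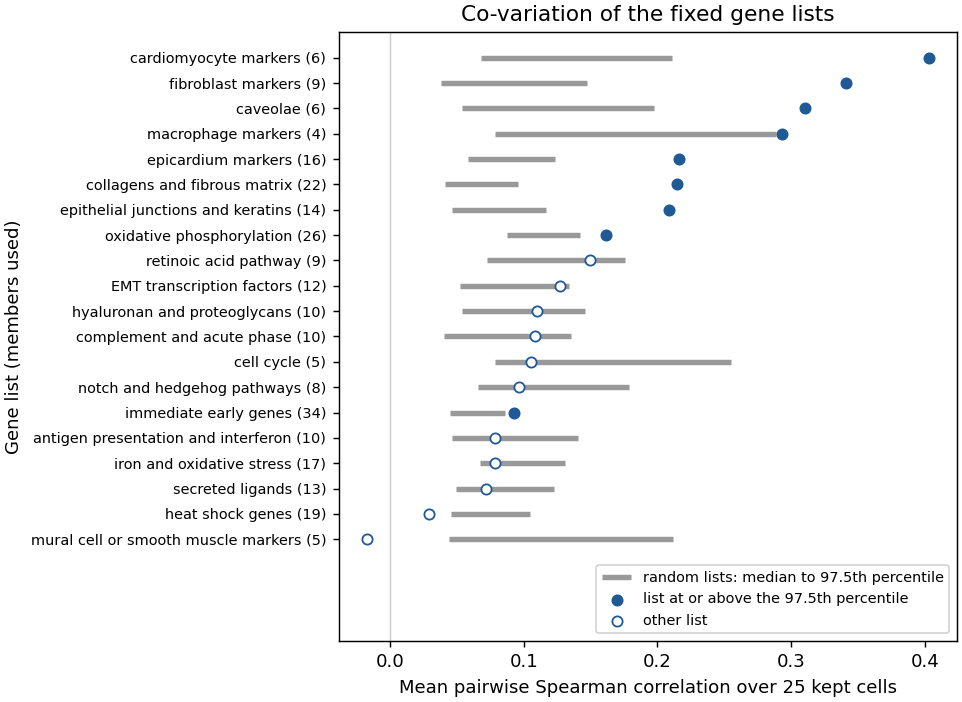
Mean pairwise Spearman correlation of the members of each gene list over the 25 kept cells (points), with grey bars from the median to the top 2.5% of 10000 matched random lists; filled points stand in the top 2.5%. The cardiomyocyte list is highest at 0.403, and the heat shock list lies at 0.0291.

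Residual variability set complement and acute phase genes apart as more variable than matched lists (percentile 99.95), and cardiomyocyte genes too (97.9), while oxidative phosphorylation genes were less variable (1.45). The last value was 17.71 without cell 40 and 55.93 over all 40 cells, complement genes stood at 73.99 over all 40 cells, and cardiomyocyte genes at 56.67 with no filter on low genes. Among genes detected in 20 to 80% of kept cells with a mean of at least 10 CPM, the highest residual variability was that of krt5, with 19554 CPM in cell 25, and cd74a, followed by the transcription factor gene BHLHE40, with 13258 CPM in cell 31. c4b, FKBP5, GAPDH, frzb, FGFR2 and CCN2 were also among the 20 most variable.

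Clustering separated 1 cell from the rest. The highest silhouette width, 0.474, was that of 2 clusters, which were cell 40 alone and the other 24 cells, and all of 100 draws of 50% of the genes gave this division. Shuffled tables reached 0.354 at most. The draws were taken from genes chosen with cell 40 included, and 7349 genes passed the filter with it, beside 5952 without it. Shuffling each gene over cells also removes differences between cells in the number of genes detected. Neither comparison thus tests whether cell 40 differs in more than its high number of genes detected. Without cell 40 the highest silhouette width was 0.246, again with 2 clusters, of 3 and 21 cells, which lay below the median of shuffled tables (0.258), and 19 of 100 draws gave the same division. Cell 40 was alone in a cluster in 12 of 15 alternative settings that included it. In the other 3, cell 11 or cell 25 was alone instead.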

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

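The tests in this part were chosen after the results they bear on had been seen, and no biological explanation was tested, since the design has 1 group. 3 signals appeared in cells that the descriptions of kept cells leave out. Cardiomyocyte markers held 18.7% of reads in cell 7 and 17.9% in cell 33. In cell 1, a single gene without a symbol, ENSDARG00000080337, held 71.4% of reads; it was named after its value was seen, and its share had a median of 2.997% in kept cells. The gene was not peculiar to that library: it held at least 26.1% of reads in each of the 5 cells with over 20% mitochondrial reads, cell 1 among them, and at most 14.1% in the others. Without a symbol it could not be counted as mitochondrial, and whether it is a mitochondrial gene was not tested.

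In cells 7 and 33 the most abundant cardiomyocyte genes were actc1a, at 80656 and 51486 CPM, and MYL7, at 57857 and 85881 CPM, although the sort was for the tcf21 reporter. Free RNA of broken cardiomyocytes would reach the other chambers too, but the median share of these markers in the other 38 cells was 0.000518% and the highest 1.13%. A cardiomyocyte captured together with a reporter cell could bring matrix transcripts of that cell, and fibroblast markers held 0.0243% of reads at most in the 2 cells, beside a median of 1.29% in kept cells. Of the other cells with TCF21 detected, only cell 1 lay lower, at 0.00384%. Its library had 161 genes and 71.4% of reads on 1 gene, so it sets a poor bound. The next lowest was cell 4 with 0.0526%. TCF21 was below the detection level in cells 7 and 33, and detected in 37 of the other 38. Epicardial markers held 0.00457% and 0.00124% of their reads, beside a median of 0.416% over all cells. Fibroblast markers were still detected in both cells, with 6 of 11 symbols in cell 7 and 7 of 11 in cell 33. Against cell 1 as the bound, the test does not decide. The low shares argue against joint capture only for a reporter cell of usual marker content that gave much of the RNA. Joint capture with a cell poor in these transcripts, or with one that gave little of the RNA, remains possible. It cannot be told apart from a cardiomyocyte that passed the sort alone. The gate would be expected to remove such a cardiomyocyte.

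Cell 40 had 10792 genes at 5 reads or more, and the next cell 4119. Thinned to 3154130 reads, the median total of the other kept cells, it still had a median of 10046.5 genes over 100 draws, so depth alone does not account for the difference. Reads leaked from other libraries would stay far below their source, but for 75.6% of the 5666 genes of cell 40 found in under 10% of the other kept cells, it held over 10% of the reads of the other 39 libraries together. RNA of several cells of different types in 1 library may add to its genes, but the test does not decide: 5 of the 12 cell type lists had 3 or more symbols at 50 CPM in cell 40, at percentile 82.84 of 10000 sets of matched random lists read in the same cell, and at 97.93 with gene copies counted apart (6 lists). Pools of 3 other kept cells at the same total had 6225 genes at most, and pools of all 24 a median of 9792.5. The pools were drawn from single-cell libraries, so transcripts missing from those libraries could not appear. They thus set no bound on the number of cells in library 40. Whether a library of many cells was included as a control was not tested.

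Genes of the heat shock list, which leaves out HSPA2, held at least 2.16% of reads in every kept cell. The highest share of all 40 cells was 21.5% in cell 4, which was not kept. RNA of damaged cells as an explanation cannot be told apart from others here: of the reads that were neither mitochondrial nor of ENSDARG00000080337, the 5 cells with over 20% mitochondrial reads had up to 2.95% on heat shock genes, above the lowest kept cell at 2.44%, but a median of 1.096% beside 5.398% in kept cells. Dissociation at 37 °C could have raised them, and cannot be told apart from the state of the cells in the fish, because no undigested cell was measured. Cells 7 and 33, digested too, had 0.387% at most, so a rise would not have been equal in every captured cell.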

How the results depend on the processing

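Settings without cell 40, with other single cells left out, with 50 CPM, on 2 principal components, or with 1000 genes beyond the count of cells kept were added after the data were seen, and the others were planned. With at least 4000 genes per cell, 2 cells were kept in place of 25, too few for clusters, co-variation or variability. Those 2 cells gave 3444 genes in every cell, 156 list genes in at least 90% of cells in place of 46, TCF21 in 100% and 1 cell with markers of another type. With any read above 0, the median was 3777 genes per cell, TCF21 was in 100% of kept cells, 582 genes were in every cell and 15 cells held markers of another type. At 20 reads 72 genes were in every cell, at 50 CPM 24, with no cell filter 41 and with 1000 genes per cell 140. At 50 CPM, 23 list genes were in at least 90% of cells and 2 cells held markers of another type. These shifts follow from the construction of the settings, which make detection stricter or looser or change the number of cells. The number of lists apart in co-variation was 9, from 7 to 10 across the other settings, and 4 without cell 40 after correction for genes detected. The number apart in variability was 3, and 1 in 4 settings: no cell filter, genes in at least 25% of cells, without cell 40, and without cells 5, 15, 25 and 40. The oxidative phosphorylation list moved from the low end of matched lists, 1.45, to near their middle, at percentiles 55.93, 58.16 and 55.54, in the first, second and last of these, and the cause was not tested. Median-of-ratios scaling gave 3 clusters in place of 2, and the cause was not tested. Across single lists, co-variation stayed on its side of the threshold in 181 comparisons, fell below it in 11 and rose above it in 12. Lists left with fewer than 4 members in a setting were not counted, such as the cardiomyocyte and macrophage lists without cell 40. For variability 9 comparisons ended a call, besides the 3 above for oxidative phosphorylation, and 3 added one. Shares of cells for genes other than TCF21 stayed within their 95% interval in 49 comparisons and left it in 21. Depth limits low genes most, since a gene with a few reads passes or fails with the detection level. The planned runs for cav1 were not run, as no symbol matched. No paired analysis was possible because the labels give 1 group.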

Other observations

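Complement and acute phase genes were read from many of the kept cells, at levels that differed widely between them. c4 was detected in 25 of 25 kept cells at 2048 ± 2561 CPM (SD over cells), from 1.81 to 10749 CPM. CLU was detected in 21, c7a in 20, c4b in 18 and cfd in 15. CLU reached 12829.6 CPM in cell 3, and c4b 14805 CPM in cell 37, with a median of 3.56 CPM for c4b. The iron carrier gene tfa was detected in 6 of 25 kept cells, with 4649 CPM in cell 37. Of the 24 measured genes of this list, 1 was detected in at least 90% of kept cells, 9 in 10 to 90% and 11 in none.

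Of 26 genes of antigen presentation and interferon response, 2 were in at least 90% of kept cells: mhc1zba, a class I gene, in 24 at 1691 ± 1414 CPM, and the beta 2 microglobulin gene b2ml in 24 at 468.3 ± 628.6 CPM. IRF7 was detected in 6 and RSAD2 in 3.

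No test was run in this part, and the next values were looked up after the data were seen. Of the 31 genes with at least 10000 reads in 1 library that made up at least 95% of all their reads, actn3b and mtus1a reached 5 reads in 0 other cells, and others reached it in up to 13. krt5 had 70075 reads in cell 25, and 7 other cells had 5 reads or more. cd74a had 62730 reads in cell 11, and 9 other cells had 5 reads or more.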
